A study of Homo sapiens with 6 samples.

How the data were processed

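Gene expression was measured by RNA sequencing in 6 libraries of MV4-11, an established human acute leukaemia cell line. Per the labels, RNA was extracted with Trizol and the libraries were made with a stranded TruSeq mRNA kit. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and the genome build hg38. Which tool did which step, the tool versions, the annotation release and whether the strand was used in counting are not given in the sources used here. The deposited values are FPKM, that is fragment counts scaled by gene length and by the mapped fragments of the library, given by the authors for 38551 Ensembl genes in 1 table with the gene symbol, biotype and position of each gene. The unit follows from the name of the deposited table and from the values, which do not sum to a fixed total and move in steps at low levels. No count table was used, and no count model was fitted. The table holds 0 further columns of per-sample values.

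Many values of weakly expressed genes lay near multiples of what 1 fragment is worth in that library, which allowed an estimate of depth. In 48.3% of the 1916 weakly expressed genes searched, all 6 values were whole multiples of 1 step, within 1% of the step or of the value. With merged exon lengths from GENCODE v29, which held 37210 of the deposited gene IDs, the depth came to about 16400000, 16100000 and 16700000 fragments in control libraries 1, 2 and 3 and to about 15700000, 16100000 and 16900000 in JOA libraries 1, 2 and 3. The deepest library held 1.08 times the fragments of the shallowest. Of 62640 values worth at most 50 such implied fragments, 82.7% lay within 0.1 of a whole number, against 20% for evenly spread values. These are estimates from the deposited values, so implied fragments were used to judge precision and not for tests. No 2 libraries of a group agreed within counting noise. The closest were control libraries 1 and 2, with a median chi-square per gene of 0.876.

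Groups and replicate numbers were taken from the sample titles. The gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Genes with an FPKM of 1 or more in at least 3 of the 6 libraries were tested, 10989 in all. The main test was limma with a mean-variance trend, two-sided, on log2(FPKM + 1) of all 6 libraries without a block, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every log2 change is on this scale, which understates the change of genes with low FPKM. The same fit with the replicate number as a block was set beside it and is called the paired fit. Whether the numbers pair the libraries was checked from the correlation, across genes, of each library's deviations from its group mean. It was 0.198 between control 1 and JOA 1, 0.243 between control 2 and JOA 2 and 0.562 between control 3 and JOA 3. All 3 exceeded 0.1, so the paired values are printed beside results whose call or count they change. The correlations of control 1 with JOA 2 and of control 2 with JOA 1 were both 0.213, so the numbers mainly set replicate 3 apart from the others. The pairing comes from these data, not from a statement in the labels.

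The 30 fixed lists were compared with all other tested genes by limma's camera at a preset correlation of 0.01, with adjustment over the 27 lists that had at least 3 tested members. The lists are monocyte and macrophage markers, granulocyte markers, phagocyte NADPH oxidase, primary granule proteins, MLL fusion and progenitor genes, MYC and ribosome biogenesis, DNA replication and E2F targets, mitosis and G2/M, CDK inhibitors and quiescence, p53 targets, BCL2 family and apoptosis, unfolded protein and integrated stress response, amino acid synthesis and transport, NRF2 and oxidative stress, heat shock, glycolysis, nuclear encoded oxidative phosphorylation, cholesterol synthesis, interferon response, NF-kB and inflammatory cytokines, JAK-STAT targets and regulators, MAPK and immediate early genes, lysosome and autophagy, MHC class II, erythroid and megakaryocyte markers, lymphoid markers, epithelial and fibroblast markers, replication-dependent histones, mitochondrially encoded genes and cytosolic ribosomal proteins. Of their 818 symbols, 34 had no match in the table.

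Genes were named by 3 rules. The first takes the 8 rises and 8 falls of greatest log2 change among genes with a symbol that pass the threshold, other than LOC, LINC, antisense and pseudogene entries, whose 3 JOA values all lie on one side of the 3 control values, and whose mean in the higher group is at least 5 FPKM. The second takes up to 3 passing members of each list with the greatest change or, where none passed, the member with the highest mean FPKM. The third takes MYC, CDKN1A, ITGAM, CD14, HOXA9, MEIS1, FLT3, CEBPA, SPI1 and BCL2 where tested. Because no gene passed in the unpaired fit, the same rules were also applied to the paired fit, a step chosen after that outcome was seen. The first rule had at first been run on protein-coding genes alone and the second on genes without overlap alone. Both were run as written after those values were seen, which put TRDD3, IGKJ1 and IGKC among the largest falls in place of CDC6, CCDC167 and POP1.

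The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, upper quartile, quantile and median ratio scaling, the replicate block, limma without a trend, each library left out in turn, camera with an estimated correlation, and fry, which asks whether a list's genes moved one way and does not compare them with other genes. Chosen after seeing the data were protein-coding genes only, genes with a mean of at least 50 implied fragments, robust variance moderation, removal of each library's trend on GC content and gene length, leaving out both libraries of a number, and all variations of the paired fit. A planned count model was not run, since the values are not counts. R 4.3.3 with limma 3.58.1 was used for tests, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the depth estimate and the plots.

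Both fits were tested on simulated data with 10792 genes for the comparison of JOA with control. Without the block, 0% of genes changed 1.25-fold, 8.16% of those changed 1.5-fold, 66.0% of those changed 2-fold and 83.0% of those changed 3-fold were recovered, and 0% of the calls were unchanged genes. With the block, the shares were 40.8%, 83.7%, 87.2% and 93.6%, and 8.18% of 159 calls were unchanged genes. That is a larger share than the threshold of 0.05 aims at. The simulation used a dispersion of 0.0007118 for all genes. It gave both libraries of a number the same deviation from the gene's mean, so its pairing was complete by construction. Here the deviation correlation was 0.198 for control 1 with JOA 1 and 0.213 for control 1 with JOA 2. The shares with the block therefore cannot be taken as the recovery of the paired fit in these libraries. Histone genes, ferritin, GAPDH, HSP90AB1, HSPD1, NCF1, KRT18, metallothioneins, immunoglobulin and T cell receptor segments, ribosomal protein genes and mitochondrially encoded genes have near-identical copies or pseudogenes, so their levels are uncertain. Overlapping and antisense genes could not be told apart if strand was not used.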

Results

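The series profiled messenger RNA in MV4-11 cells, a human acute leukaemia line that carries a KMT2A-AFF1 fusion and an internal tandem duplication of FLT3. It asked which transcripts differ after 48 h with an agent that the titles call JOA. Cells given JOA (3 libraries) were set against control cells (3 libraries). The dose field of the JOA libraries reads 0.5 µM but names the agent as I13, so the dose rests on that field, and neither name is expanded in the labels. The authors deposited FPKM, and 10989 genes with at least 1 FPKM in at least 3 libraries were tested. The estimated depth was 15700000 to 16900000 fragments per library. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

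JOA and control libraries were similar as a whole. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.982 to 0.991 between control libraries, 0.970 to 0.982 between JOA libraries and 0.965 to 0.986 between groups. The first principal component held 37.5% of the variance and set both libraries numbered 3 apart from the other 4. The second held 32.1% and placed control libraries 1 and 2 at the opposite end from JOA libraries 1 and 3. In the pair of replicate 1 the log2 difference of JOA and control exceeded the mean of the other pairs by at least 2-fold in 146 genes and fell short of it in 113. In 86 of the 146 genes JOA 1 lay at least 2-fold above both JOA 2 and JOA 3. Among these was RPS15, a ribosomal protein gene, at 631 FPKM in JOA 1 and 134 and 146 FPKM in JOA 2 and JOA 3.

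**Figure D1:**
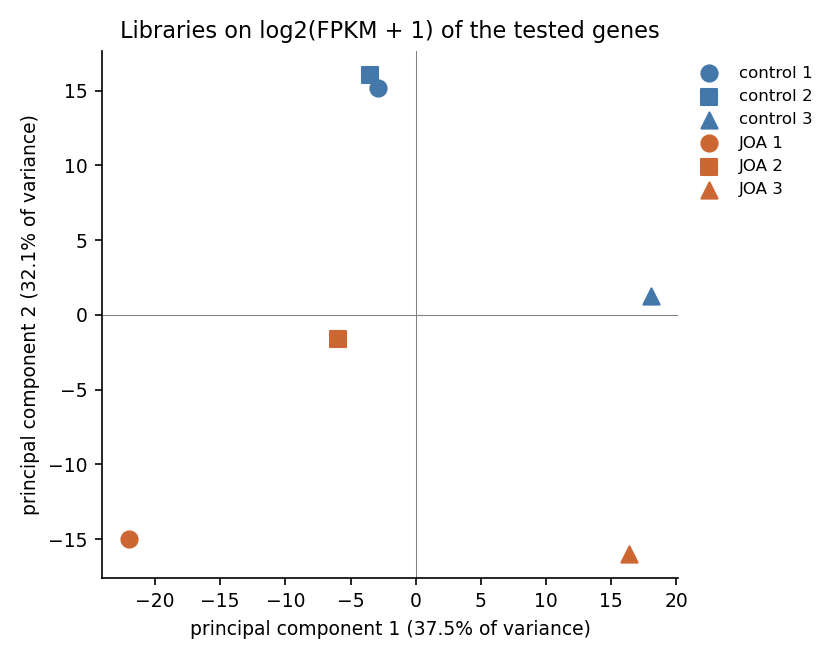
Scores of the 6 libraries on the first (37.5% of variance) and second (32.1%) principal components of log2(FPKM + 1) over 10989 genes, with colour for group and shape for replicate number. Control 3 and JOA 3 lie to the right at 18.1 and 16.4, while JOA 1 lies at -22.0 on the first component.

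As lists, genes of DNA replication and mitosis were lower in JOA-treated cells, and p53 targets, lysosomal genes, granulocyte and monocyte markers and genes of the phagocyte NADPH oxidase were higher, at a preset correlation within each list. Only members that passed the expression filter were tested, 6 of 19 matched granulocyte markers and 18 of 29 matched monocyte and macrophage markers. With an estimated correlation, 2 lists passed without the block, DNA replication and p53 targets, both at an adjusted p = 0.0367. With the block 0 lists passed, the smallest adjusted p being 0.122. The changes were small. The median log2 change was -0.38 over 43 DNA replication and E2F target genes, -0.30 over 37 mitosis genes, 0.37 over 22 p53 targets and 0.25 over 35 lysosome and autophagy genes. All 43 replication genes and all 37 mitosis genes had a negative log2 change. Of the 27 gene lists tested with limma's camera, 14 passed the threshold, 7 higher and 7 lower. With quantile normalization the split was 10 higher and 4 lower. In the paired fit 17 lists passed, 9 higher and 8 lower, and 10 higher and 5 lower with quantile normalization.

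Gene by gene, limma without the block called 0 of 10989 genes, the smallest adjusted p being 0.0847. At an unadjusted p under 0.05 it found 1738 genes, 933 higher and 805 lower, where about 549 would be expected by chance. Other splits of the 6 libraries into 3 and 3 gave from 101 to 1266 such genes. Each of those splits mixes the groups unevenly and so still holds part of any difference between them. The splits therefore cannot decide whether the excess over 549 is evidence of a difference between the groups. Limma with the replicate number as a block called 406 genes, 191 higher and 215 lower, of which 2 rose and 4 fell by at least 2-fold. Of these 406 genes 363 were protein-coding. The median fold among called genes was 1.36 for rises and 0.768 for falls. In 345 of the 406 genes the 3 JOA values did not overlap the 3 control values, as in 22.8% of all tested genes, against 10% by chance. The paired count was 0 without replicate 2, 0 without replicate 3 and 922 without replicate 1, and it was also 0 without an expression filter or without a variance trend. Removing each library's trend on GC content and length gave 120 genes without the block. All adjusted p-values of called genes lay between 0.0421 and 0.0498.

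The 8 largest rises in the paired fit were those of SEMA6B, H2AC6, CDKN1A, ADA2, H2BC12, FUCA1, HMOX1 and CYP27A1. SEMA6B, which encodes a transmembrane semaphorin (ENSG00000167680, hg38 chromosome 19, 4542593 to 4581776), rose from 9.05 ± 0.626 to 20.8 ± 5.37 FPKM (SD, n = 3 each). CDKN1A, the cyclin-dependent kinase inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687337), went from 91.7 ± 21.5 to 174 ± 47.3 FPKM. Its log2 change was 0.91, with a standard error of 0.258 and a limma adjusted p = 0.179 without the block, and a standard error of 0.0482 and an adjusted p = 0.0421 with it. ADA2, a secreted adenosine deaminase (chromosome 22, 17178790 to 17258235), rose by a log2 change of 0.91, from 5.92 ± 0.281 to 12.1 ± 1.73 FPKM. FUCA1, the lysosomal fucosidase, rose by 0.84, HMOX1, the inducible haem oxygenase, by 0.81, and CYP27A1, the mitochondrial sterol 27-hydroxylase, by 0.76. The histone genes H2AC6 and H2BC12 rose by 1.01 and 0.88, although both belong to a family of near-identical genes.

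The 8 largest falls were those of TRDD3, IGKJ1, IGKC, PHGDH, TNF, MCM7, FABP5 and RFC3. TRDD3, a T cell receptor delta diversity segment of 13 bases (chromosome 14, 22449113 to 22449125), had 6.23 ± 2.56 FPKM in control libraries and was listed at 0 in all 3 JOA libraries. At the estimated depth its control values are worth about 1, 1 and 2 fragments, too few to show a difference. IGKC, the constant segment of the immunoglobulin kappa locus (chromosome 2, 88857161 to 88857683), fell from 27.2 ± 5.17 to 15.9 ± 3.70 FPKM, and its joining segment IGKJ1, of 38 bases, from 20.7 ± 12.03 to 8.59 ± 3.37 FPKM, worth about 8 to 22 and 4 to 8 fragments. The log2 change of IGKJ1 was -1.10, and -0.68 without control replicate 3 and without the block. PHGDH, the first enzyme of serine synthesis (ENSG00000092621, chromosome 1, 119648411 to 119744218), fell from 8.81 ± 0.940 to 4.998 ± 0.641 FPKM, a log2 change of -0.71 ± 0.0447 (SE) in the paired fit. TNF, the inflammatory cytokine (chromosome 6, 31575565 to 31578336), fell from 7.73 ± 0.874 to 4.93 ± 0.637 FPKM. The log2 change was -0.55 for MCM7 of the replicative helicase (chromosome 7, 100092728 to 100101940), -0.54 for FABP5, a fatty acid binding protein gene, and -0.53 for RFC3 of the clamp loader. None of these 8 genes passed in the main test without the block, where the limma adjusted p was 0.0847 for TRDD3, PHGDH, MCM7 and RFC3, 0.105 for TNF, 0.133 for FABP5, 0.147 for IGKC and 0.260 for IGKJ1. After the GC and length correction, TRDD3, PHGDH, MCM7 and RFC3 passed without the block.

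**Figure D2:**
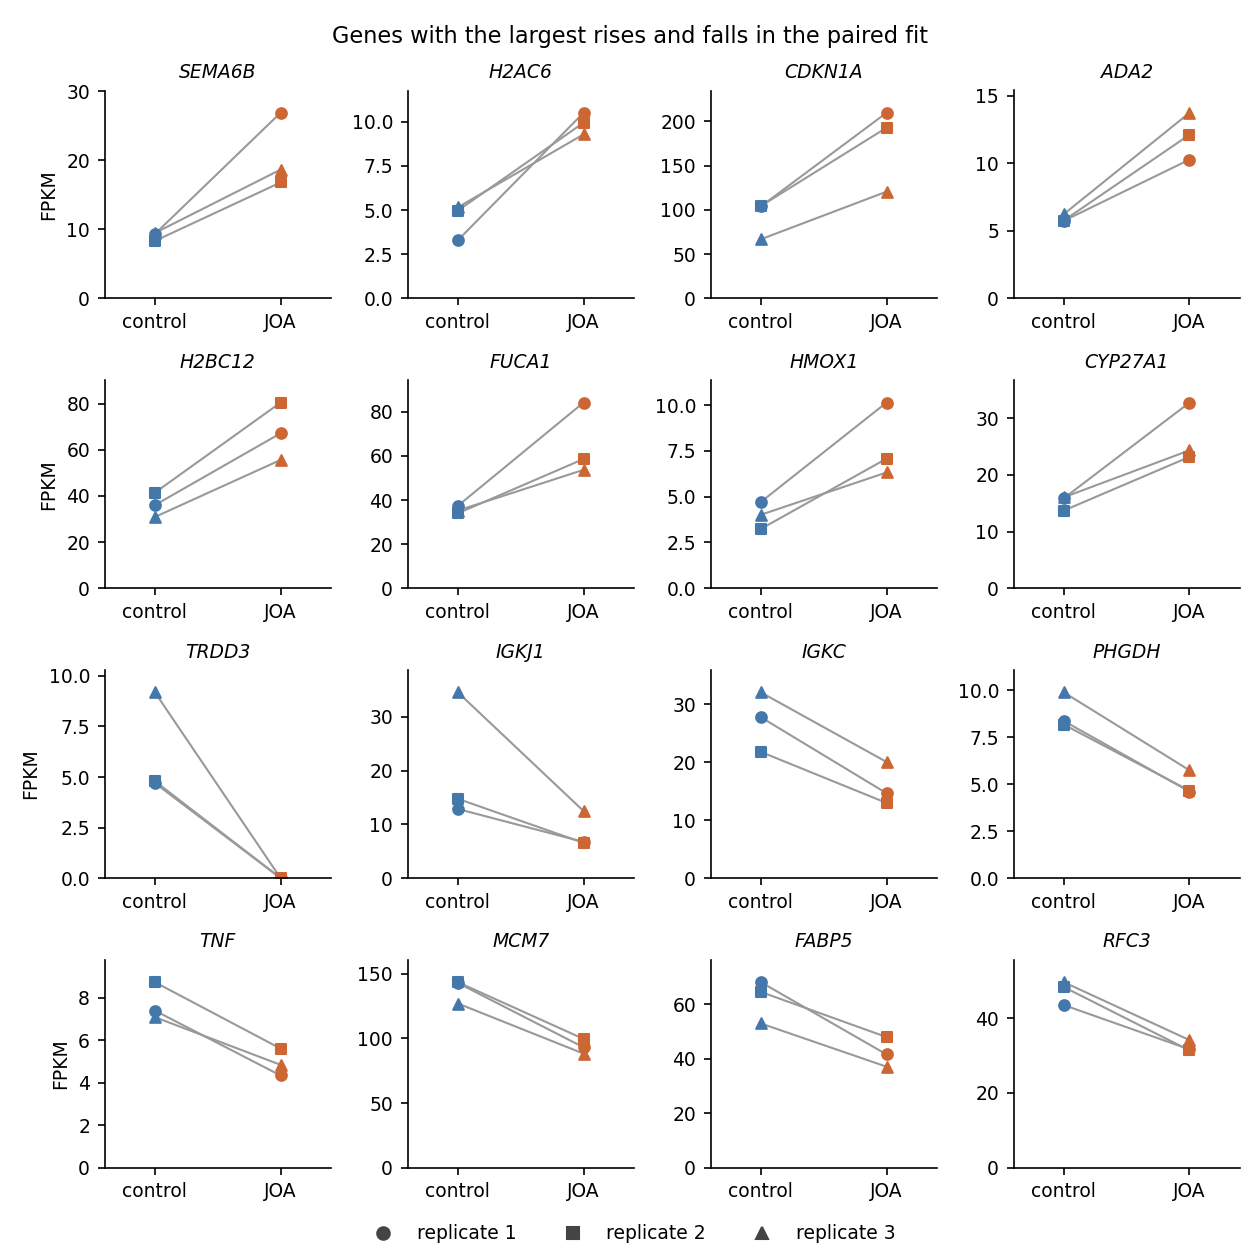
FPKM in each library (vertical axes from 0) of the 8 genes with the largest rises and the 8 with the largest falls in the paired fit, in control (blue) and JOA (orange) libraries, with lines joining libraries of the same number. CDKN1A lies between 66.8 and 104 FPKM in control libraries and between 121 and 210 FPKM in JOA libraries.

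The list of DNA replication and E2F targets fell in JOA-treated cells (camera in limma, adjusted p = 2.3e-31, and adjusted p = 0.0367 with an estimated correlation, which became 0.122 with the block). Of its 43 tested members 40 were lower in all 3 pairs, where chance gives 12.5% in a given direction. For either direction chance gives 25%, and 54.8% of all tested genes moved the same way, higher or lower, in all 3 pairs. Without the block 0 members passed over all genes and 35 passed, all lower, when adjusted over the list alone. With the block 24 passed over all genes and 39 when adjusted over the list alone, again all lower. CDC6 of the origin licensing machinery fell from 18.8 ± 0.571 to 12.8 ± 0.604 FPKM in that fit. PCNA, the sliding clamp and the most abundant member, had 455 ± 9.06 FPKM in control and 388 ± 20.2 FPKM in JOA libraries, with a log2 change of -0.23 that passed in neither fit. The mitosis and G2/M list fell as well (adjusted p = 2.44e-18), but at adjusted p = 0.108 with an estimated correlation it did not pass. Of its 37 tested members 34 were lower in all 3 pairs, 22 passed when adjusted over the list alone without the block, and 15 passed over all genes in the paired fit. In the paired fit AURKB, a mitotic kinase gene, fell by 0.45 on the log2 scale, BIRC5, which encodes survivin, by 0.44 and BUB1B of the spindle checkpoint by 0.43. None of them passed without the block, and the groups overlapped for BIRC5. CKS2, a cyclin-dependent kinase subunit, had 131 ± 0.768 and 97.9 ± 7.74 FPKM and likewise passed in the paired fit only (adjusted p = 0.0444).

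The tested replication-dependent histones, which are normally made in S phase, moved opposite to the replication list. Of the 48 symbols on their list, 24 matched a deposited gene and 11 were tested. The libraries were made with an mRNA kit, and how fully it captures histone transcripts was not tested. These values are therefore no measure of S phase. The list rose (median log2 change 0.48, adjusted p = 5.3e-06), with adjusted p = 0.181 with an estimated correlation. All 11 tested members had a positive log2 change, and 8 passed when adjusted over the list alone without the block. Only H2AC6 (4.47 ± 1.02 to 9.90 ± 0.610 FPKM) and H2BC12 (36.1 ± 5.26 to 67.7 ± 12.4 FPKM) passed over all genes in the paired fit. The median of the list was 0.78 in the pair of replicate 1, against 0.51 and 0.48 in the pairs of replicates 2 and 3.

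The p53 target list rose (adjusted p = 4.05e-09, and adjusted p = 0.0367 with an estimated correlation, which became 0.279 with the block). Of 22 tested members, 18 were higher in all 3 pairs and 14 passed, all higher, when adjusted over the list alone without the block. With the block 9 passed over all genes and 18 when adjusted over the list alone. Besides CDKN1A, TP53INP1 rose from 5.39 ± 0.806 to 9.06 ± 2.01 FPKM, and BTG2, an antiproliferative gene, from 10.01 ± 1.21 to 15.7 ± 1.80 FPKM in the paired fit. BBC3, which encodes the pro-apoptotic protein PUMA, rose by a log2 change of 0.57. BAX, the most abundant member of the BCL2 family and apoptosis list, had 67.4 ± 8.17 and 80.5 ± 5.65 FPKM, with adjusted p = 0.315 without the block and 0.0550 with it. That list of 22 tested genes did not pass (adjusted p = 0.525), with BBC3 called higher and BIRC5 lower in the paired fit, and 3 higher and 1 lower when adjusted over the list alone without the block. The CDK inhibitors and quiescence list did not pass either (adjusted p = 0.11), with 1 of 15 members higher when adjusted over the list alone without the block and CDKN1A and BTG2 called in the paired fit. The CDK inhibitors and quiescence list passed as higher without an expression filter (0.0318, and 0.0164 in the paired fit). Fry, which tests a list's genes against no change and not against other genes, gave it an adjusted p = 0.0353, and 0.0212 in the paired fit.

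The lysosome and autophagy list rose (adjusted p = 6.94e-09, and adjusted p = 0.158 with an estimated correlation), with 28 of 35 tested members higher in all 3 pairs, 6 passing when adjusted over the list alone without the block and 5 passing over all genes in the paired fit. PSAP, the precursor of the saposins (ENSG00000197746, chromosome 10, 71816298 to 71851325), rose from 194 ± 6.20 to 268 ± 4.21 FPKM, GAA, the acid glucosidase gene, from 15.2 ± 1.88 to 23.6 ± 1.64 FPKM, and TFE3, a transcription factor gene of the lysosomal programme, from 13.5 ± 1.82 to 17.6 ± 2.95 FPKM in the paired fit. The groups overlapped for TFE3. The granulocyte list rose (adjusted p = 0.00027, and adjusted p = 0.108 with an estimated correlation). Of its 19 genes in the deposited data only 6 passed the expression filter, so the result covers those alone. All 6 tested granulocyte genes were higher in all 3 pairs, 5 passed when adjusted over the list alone without the block and 3 passed over all genes in the paired fit. CSF3R, the G-CSF receptor gene, rose from 36.2 ± 3.64 to 53.2 ± 3.37 FPKM and ALOX5, the 5-lipoxygenase gene, from 1.68 ± 0.496 to 2.86 ± 0.586 FPKM in that fit, and ALOX5AP, its activating protein gene, by a log2 change of 0.37, with groups that overlapped. Without the block, the change of ALOX5AP was 0.11 without control replicate 3, 0.21 without JOA replicate 1 and 0.63 without JOA replicate 3.

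The phagocyte NADPH oxidase list rose (adjusted p = 0.0124) but not with an estimated correlation (adjusted p = 0.438), without JOA replicate 1 (0.0765), without control replicate 3 (0.14), after the GC and length correction (0.0616) or with fry (0.147). All 6 members of phagocyte NADPH oxidase were higher in all 3 pairs, and 1 passed when adjusted over the list alone without the block. In the paired fit 3 passed, among them CYBB, the catalytic subunit gene, which rose by a log2 change of 0.67, and NCF1, which rose by 0.49 (0.28 without control replicate 3 and 0.32 without JOA replicate 1, both without the block), each with groups that overlapped. RAC2, its most abundant member, had 147 ± 6.77 and 159 ± 11.2 FPKM and did not pass. Monocyte and macrophage markers rose as a list (median log2 change 0.22, adjusted p = 0.00322), but at adjusted p = 0.438 with an estimated correlation, 0.13 without control replicate 3, 0.0508 without JOA replicate 2 and 0.144 with fry they did not pass. Of 29 such markers in the deposited data 18 passed the expression filter. Of 18 tested monocyte and macrophage markers 14 were higher in all 3 pairs, and 1 passed when adjusted over the list alone without the block. In the paired fit ITGAX, which encodes CD11c, rose from 2.51 ± 0.182 to 4.13 ± 0.373 FPKM and MNDA, a myeloid nuclear antigen gene, from 27.1 ± 6.48 to 33.9 ± 9.33 FPKM, with groups that overlapped. Without the block, the log2 change of 0.30 for MNDA was 0.09 without control replicate 3, 0.19 without JOA replicate 1, 0.17 without JOA replicate 2 and 0.55 without JOA replicate 3. LYZ, the lysozyme gene, had 1921 ± 161 and 2352 ± 249 FPKM and passed in neither fit. ITGAM, which encodes CD11b, had 4.31 ± 0.493 and 6.95 ± 2.12 FPKM and did not pass either, with adjusted p = 0.277 without the block and 0.0755 with it. CD14 stayed below 1 FPKM in all 6 libraries and was not tested. Primary granule proteins did not pass as a list (adjusted p = 0.32), with 2 of 11 members higher when adjusted over the list alone without the block. SRGN, their most abundant member, had 5580 ± 46.6 and 7373 ± 218 FPKM (adjusted p = 0.0880 without and 0.0581 with the block), and SERPINB1 rose from 71.2 ± 0.283 to 88.8 ± 1.80 FPKM in the paired fit.

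**Figure D3:**
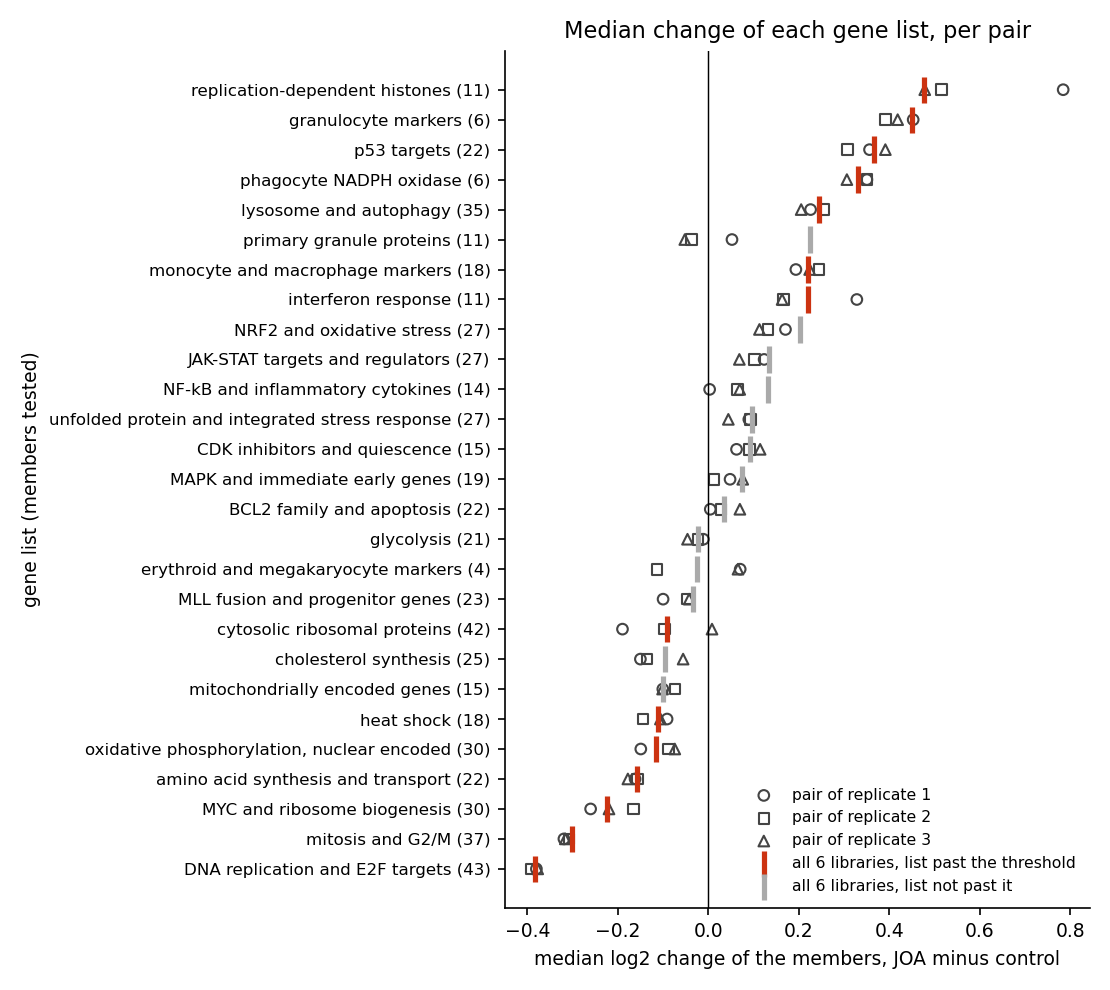
Median log2 change (JOA minus control, horizontal axis) of the members of each of the 27 tested gene lists, with the number of tested members in brackets, open symbols for the 3 pairs and bars for the median over all 6 libraries, red where the list passed camera without the block. The DNA replication list lies at -0.38 in all 6 libraries and at -0.38, -0.39 and -0.38 in the pairs.

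Genes of ribosome production and of amino acid supply were lower. The MYC and ribosome biogenesis list fell (median log2 change -0.22, adjusted p = 4.49e-11, and adjusted p = 0.158 with an estimated correlation), with 25 of 30 tested members lower in all 3 pairs, 11 passing when adjusted over the list alone without the block and 6 passing over all genes in the paired fit. NOP56 of the box C/D ribonucleoproteins fell from 80.03 ± 3.55 to 61.4 ± 1.95 FPKM, PAICS of purine synthesis from 46.7 ± 0.370 to 36.3 ± 1.14 FPKM and RCC1, the nucleotide exchange factor of RAN, from 66.3 ± 3.28 to 52.1 ± 3.08 FPKM in that fit. APEX1, the most abundant member, had 274 ± 25.7 and 242 ± 23.3 FPKM and did not pass. MYC itself had 119 ± 8.06 FPKM in control and 122 ± 13.9 FPKM in JOA libraries, a log2 change of 0.03 (adjusted p = 0.926). Amino acid synthesis and transport genes fell (median log2 change -0.16, adjusted p = 5.3e-06, and adjusted p = 0.102 with an estimated correlation), with 7 of 22 tested members passing, all lower, when adjusted over the list alone without the block and 5 over all genes in the paired fit. Besides PHGDH, SLC1A5, a glutamine transporter gene, fell from 43.8 ± 2.52 to 31.8 ± 3.62 FPKM and PSAT1, the serine synthesis transaminase, from 60.03 ± 6.29 to 47.8 ± 4.62 FPKM in the paired fit.

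A further 4 lists passed without the block. Cytosolic ribosomal proteins fell (median log2 change -0.09, adjusted p = 0.00027, and adjusted p = 0.460 with an estimated correlation) with 0 of 42 members called in either fit, over all genes or when adjusted over the list alone. Their median was -0.19 and -0.097 in the pairs of replicates 1 and 2, but 0.008 in the pair of replicate 3. Of the 42 members 18 were lower and 2 higher in all 3 pairs. Cytosolic ribosomal proteins did not pass with quantile normalization (0.508), without both libraries of replicate 1 (0.0576) or with fry (0.205). Heat shock genes fell (median -0.11, adjusted p = 0.00506, and adjusted p = 0.315 with an estimated correlation), but the heat shock call was lost with quantile normalization (0.119), without JOA replicate 3 (0.0572) and with fry (0.0652). Of their 18 tested members 2 were higher and 6 lower when adjusted over the list alone without the block. HSPD1, the mitochondrial chaperonin, fell from 132 ± 3.25 to 108 ± 4.78 FPKM in the paired fit, and HSP90AB1 had 1158 ± 4.95 and 982 ± 31.4 FPKM and did not pass. Nuclear encoded oxidative phosphorylation genes fell (median -0.12, adjusted p = 0.0204, and adjusted p = 0.638 with an estimated correlation), with 0 of 30 members passing when adjusted over the list alone without the block. In the list of oxidative phosphorylation, nuclear encoded, the call was lost with quantile normalization (0.239), at 5 FPKM (0.0966), without control replicate 1 (0.241), control replicate 2 (0.115) or JOA replicate 3 (0.783), without both libraries of replicate 1 (0.0864) and with fry (0.591). NDUFB6 of complex I fell from 21.8 ± 2.25 to 17.0 ± 1.75 FPKM in the paired fit, while ATP5F1B had 498 ± 36.9 and 547 ± 85.8 FPKM. Genes of the interferon response rose (median 0.22, adjusted p = 0.00974, and adjusted p = 0.158 with an estimated correlation), but not without an expression filter (0.164). Only 11 of the 35 interferon response genes in the deposited data passed the expression filter. Of 11 tested members 1 passed when adjusted over the list alone without the block and 3 rose in the paired fit, IFI35 by a log2 change of 0.61, STAT2 by 0.43 and BST2 by 0.30 (0.20 without control replicate 3 and without the block).

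A further 3 lists passed with the block and missed the threshold without it, where 0 of their members passed when adjusted over the list alone. The cholesterol synthesis list had an adjusted p = 0.0558 without and 0.00556 with the block (median log2 change -0.09), and without the block it passed without control replicate 3 (0.000195), JOA replicate 1 (0.0352), JOA replicate 2 (0.00683) or both libraries of replicate 3 (0.0112), without an expression filter (0.0239), with protein-coding genes only (0.0483) and after the GC and length correction (0.0468), while the paired call was lost with fry (0.0924). In the paired fit ACAT2 had a log2 change of -0.34 (-0.21 without JOA replicate 3 and without the block) and TM7SF2 one of 0.43 (0.23 without control replicate 3 and without the block), both with groups that overlapped, while SQLE, the most abundant member, had 62.7 ± 6.96 and 64.4 ± 10.9 FPKM. The list of NRF2 and oxidative stress had an adjusted p = 0.064 and 0.0245 (median 0.20), passing without the block when control replicate 1 (0.0116) or JOA replicate 3 (0.0137) or both libraries of replicate 1 (0.0341) or 3 (0.0253) were left out, without an expression filter (0.0272) and with quantile normalization (0.0124), and failing with it without replicate 2 (0.0658) and at 5 FPKM (0.0712). In the paired fit HMOX1 rose from 3.99 ± 0.736 to 7.85 ± 2.02 FPKM, while AKR1B1 had a log2 change of -0.38 (-0.25 without JOA replicate 3 and without the block), with groups that overlapped. FTL, the ferritin light chain gene, had 6780 ± 1282 and 8195 ± 1409 FPKM. JAK-STAT targets and regulators had an adjusted p = 0.0524 and 0.0168 (median 0.13) with 0 members called, passing without the block when control replicate 1 (0.0373), control replicate 2 (0.0467) or JOA replicate 3 (0.00784) or both libraries of replicate 3 (0.0115) were left out, without an expression filter (0.0415), at 5 FPKM (0.00729) and with quantile normalization (0.0287), and failing with it without replicate 1 (0.109), after the GC and length correction (0.0972) and with fry (0.0855), PTPN6 lying at 88.6 ± 7.29 and 91.1 ± 7.63 FPKM. With an estimated correlation the paired adjusted p of these lists was 0.294, 0.294 and 0.389.

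Genes of the leukaemic progenitor state were called in neither fit. The list of MLL fusion and progenitor genes did not pass (median log2 change -0.03 over 23 genes, adjusted p = 0.133), and 0 members passed when adjusted over the list alone. Without control replicate 1, control replicate 2 or JOA replicate 3 it passed as lower, at an adjusted p of 0.0287, 0.0313 and 0.00251, and with the block it passed without replicate 3 (0.0485), without an expression filter (0.0104) and with median ratio scaling (0.0499). HOXA9 had 13.4 ± 1.30 FPKM in control and 14.9 ± 2.34 FPKM in JOA libraries, MEIS1 3.55 ± 0.589 and 3.14 ± 0.753, FLT3 85.5 ± 7.997 and 83.4 ± 7.96, and BCL2 15.6 ± 2.11 and 13.2 ± 2.57. The myeloid transcription factor genes CEBPA and SPI1 had 54.0 ± 8.21 and 53.7 ± 4.61 FPKM, and 118 ± 4.76 and 135 ± 13.1 FPKM. The adjusted p of these 6 genes was at least 0.353 without the block and at least 0.0749 with it.

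Other lists that passed in neither fit were unfolded protein and integrated stress response (adjusted p = 0.144), NF-kB and inflammatory cytokines (0.272), MAPK and immediate early genes (0.465), glycolysis (0.827) and mitochondrially encoded genes (0.133). The list of unfolded protein and integrated stress response passed as higher without JOA replicate 3 (0.0216) and with quantile normalization (0.0287, and 0.0214 in the paired fit). Mitochondrially encoded genes passed as lower without JOA replicate 2 (0.0407), without both libraries of replicate 2 and with protein-coding genes only, all without the block. When adjusted over the list alone without the block, 1 member passed in the stress response list, 1 in each direction in the NF-kB list, 0 in the MAPK list, 1 in the glycolysis list and 0 of the mitochondrial genes. Within them CALR had 643 ± 29.5 and 588 ± 107 FPKM, CXCL8 18.1 ± 1.76 and 25.5 ± 6.31 and MT-CO1 12360 ± 1286 and 13810 ± 111. PPP1R15A, a stress-induced phosphatase subunit gene, rose from 13.2 ± 1.13 to 17.9 ± 0.643 FPKM in the paired fit, DDIT4, a stress-induced inhibitor of mTORC1 signalling, by a log2 change of 0.35 (without the block -0.02 without control replicate 3, 0.55 without control replicate 2, 0.15 and 0.14 without JOA replicates 1 and 2 and 0.76 without JOA replicate 3), MT-ATP8 fell from 23.9 ± 3.82 to 17.4 ± 2.42 FPKM, and GAPDH from 1099 ± 166 to 867 ± 162 FPKM (paired adjusted p = 0.0488), with a log2 change of -0.35, or -0.19 without JOA replicate 3 and without the block. The groups overlapped for DDIT4 and for GAPDH. The glycolysis list had a negative median (-0.02), a positive mean (0.04) and a positive camera direction without the block, which was negative with it.

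Markers of other cell types were mostly near the detection floor. Of 20 epithelial and fibroblast markers, 18 stayed below 1 FPKM in all libraries, as did 19 of 23 erythroid and megakaryocyte markers, 20 of 22 lymphoid markers and 8 of 11 MHC class II genes. Among the exceptions were KRT18 (1.43 ± 0.304 in control and 1.402 ± 0.529 FPKM in JOA libraries), ACTA2 (0.833 ± 0.223 and 1.65 ± 0.257), NFE2 (25.5 ± 0.970 and 27.3 ± 0.0199), NKG7 (69.9 ± 10.2 and 64.9 ± 8.79) and CD74 (48.3 ± 5.99 and 45.4 ± 5.62). None of these 5 genes passed over all genes in either fit, and ACTA2 passed when adjusted over the list alone without the block. The erythroid and megakaryocyte list did not pass (adjusted p = 0.958, 4 genes tested), and the others had too few tested members for a test.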

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

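Tests chosen after the results were seen are the GC and length correction, the filters on biotype and implied fragments, robust variance moderation, leaving out a replicate number and all variations of the paired fit. The unpaired count of 0 genes became 1 with a pseudocount of 0.1 or 0.5, 120 with the GC and length correction and 406 with the replicate block. It ranged from 0 to 1 with libraries left out. The single gene was TRDD3 each time, 13 bases long, with about 1, 1 and 2 implied fragments in control libraries and 0 in JOA libraries. The paired count of 406 became 0 with no filter, 0 with eBayes without trend, 0 with no replicate block, 853 at FPKM 5 or more, 1120 with protein-coding genes only, 1013 with at least 50 implied fragments and 792 with the GC and length correction. It ranged from 0 to 922 with a replicate left out. The adjusted p of the 406 genes lay between 0.0421 and 0.0498, close to the threshold, and the cause of these moves was not tested. The 14 lists became 2, and the paired 17 became 0, with an estimated correlation, and both counts stayed within 1.5 times under every other alternative run. The replicate block changed no other call than those given with the results. Of 1791 values of named genes under alternatives to the unpaired fit, 1690 kept direction and side of the threshold. That fit called 0 genes, so these 1690 values are of genes that stayed uncalled. The paired calls of single named genes were not followed under alternatives, so these values do not measure how stable those calls are. For lists, 543 of 620 values kept direction and side of the threshold, and 412 of 458 did in the paired fit. Camera offers no robust moderation, and a count model was not run, since the values are not counts.

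Apart from DDIT4, called in the paired fit and turned in the unpaired one, directions turned only for genes and lists that passed in neither fit, and the cause was not tested. For log2 changes, these were FLT3 (0.012 with quantile normalization, 0.0090 with the GC and length correction, -0.10 to 0.036 with libraries left out), PTPN6 (-0.023 with that correction, -0.025 to 0.11 left out), CEBPA (0.045 with quantile normalization, -0.13 to 0.081 left out), and, with libraries left out, CALR (-0.26 to 0.0058), SQLE (-0.086 to 0.16), MYC (-0.047 to 0.12), CD74 (-0.18 to 0.0084), NKG7 (-0.23 to 0.011), KRT18 (-0.16 to 0.16), HOXA9 (-0.0015 to 0.26) and DDIT4 (-0.020 to 0.76). The glycolysis list turned at an adjusted p of 0.896 (GC and length), 0.689 (replicate block), and 0.684 (quantile), 0.827 (no block) and 0.917 (fry) from the paired fit, ranging from 0.166 to 0.909 unpaired and 0.491 to 0.885 paired with libraries left out. The erythroid list turned at 0.859 (fry) and 0.917 (paired fry), ranging from 0.526 to 0.965 and 0.799 to 0.885. At 5 FPKM the paired BCL2 family list turned at 0.833 and the NF-kB list at 0.989. At 3 libraries a group and the depth of these, 8.16% of 49 changes of 1.5-fold were recovered without the block in simulated data. The simulation gave both libraries of a number the same deviation and all genes the same dispersion, so the share in these libraries may differ.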

Other observations

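The tests of scaling, of JOA replicate 1 alone, of replicate 1 within its own group, of the share of pseudogenes with its interval and of the gene counts over other splits were chosen after the results were seen, as were the biological process terms named here. Of 1345 terms in the deposited annotation with 10 to 200 tested genes, camera put 147 past the threshold, 45 higher and 102 lower, and 133 of them in the same direction in the paired fit. With an estimated correlation 0 passed, the smallest adjusted p being 0.431. The overlap of the terms named here with the fixed lists was not measured. The term mRNA splicing, via spliceosome was lower as a set (193 genes, median log2 change -0.11, adjusted p = 1.62e-06), with 5 of its genes called lower in the paired fit. The 35 genes of interstrand cross-link repair had a median of -0.19 (adjusted p = 1.29e-06) and the 78 genes of mitochondrial translational elongation one of -0.09 (adjusted p = 0.00161). In each of these 2 terms 1 gene was called lower in the paired fit. Higher as sets were interferon-gamma-mediated signaling (34 genes, median 0.22, adjusted p = 0.000118), integrin-mediated signaling (44 genes, 0.13, adjusted p = 0.00286) and glycosphingolipid metabolism (19 genes, 0.25, adjusted p = 0.00706), with 2, 4 and 2 genes called higher in the paired fit.

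Genes of replication and mitosis were lower as lists in JOA libraries, with a median log2 change of -0.335 over the 80 members of both lists and quartiles of -0.419 and -0.243, and with an estimated correlation the adjusted p was 0.0367 for replication and 0.108 for mitosis without the block and 0.122 for both with it. GC content and length bias is argued against, since the median kept 96.8% of its size after the correction in the paired fit, where 47 instead of 39 members were called lower. The choice among the scalings run is argued against as well, because the median log2 change of all genes was 0.0217 under the deposited scaling, and the median of the lists stayed between -0.352 and -0.329 under the other 3 scalings. Each of these scalings brings the libraries to a common level, so a change in total RNA per cell could not be seen. The pattern did not rest on JOA replicate 1, for in the pairs of replicates 2 and 3 the median nearest to 0 was -0.34. An effect of the treatment on proliferation may account for it, as a hypothesis from these libraries that was not itself tested, and a batch or culture difference between the groups stays open. The replication-dependent histone list, with 11 tested members, rose instead (median log2 change 0.48).

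The pair of replicate 1 departed from the other pairs, its log2 difference exceeding their mean by at least 2-fold in 146 genes and falling short of it in 113, against an excess in 84 and 81 genes in the pairs of replicates 2 and 3. The highest were GPX1P1, a processed pseudogene, at 148 FPKM in JOA 1 against 6.37 and 5.97 in JOA 2 and JOA 3, and FTH1, the ferritin heavy chain gene, at 35.2 against 1.399 and 2.07 FPKM. GC content bias may contribute, because the excess rose with GC content over all genes (Spearman rho 0.273, across genes). JOA 1 minus JOA 2 and JOA 3 rose with it as well (0.466). So did control 1 minus the other controls (0.313), which by itself would lower the excess. Both contrasts include replicate 3, whose difference from the others fell with GC content (-0.364 in control, -0.47 in JOA). The excess of the pairs of replicates 2 and 3 fell with it (-0.137 and -0.254), so the trend cannot be laid to replicate 1 alone. Reads shared with pseudogenes cannot be told apart from other causes, because the share of protein-coding genes in excess with a named pseudogene was 0.927 times that among all (9 of 84 genes, 10.7%, exact 95% interval 5.02% to 19.4%, against 11.6%), while pseudogenes made up 16.4% of the genes in excess and 6.2% of all tested genes. The median of 87.5 implied fragments over the 146 genes did not decide on lower depth. JOA 1 held about 15700000 fragments, against 16100000 and 16900000 in JOA 2 and JOA 3. For the 72 of the 146 genes above 100 implied fragments, so small a difference argues against lower depth. For the other genes lower depth cannot be told apart from other causes, and no biological explanation was tested.

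Libraries numbered 3 differed from the others in both groups, with 30 genes at least 2-fold apart in both, 14 higher and 16 lower, against 8 and 11 for numbers 1 and 2. MT2A, a metallothionein gene, had 27.1 and 14.6 FPKM in control 3 and JOA 3 and 228, 211, 60.1 and 127 FPKM in the others. In S100A9, a calprotectin subunit gene, the values were 20.01 and 21.9 FPKM against 81.9 to 98.4 FPKM. These genes had a median of 129.3 implied fragments, which argues against depth for the genes above that median only. The 30 genes include short RNAs such as MIR548AT, at 0, 0 and 1.03 FPKM in control libraries 1, 2 and 3. For the genes below the median, depth cannot be told apart from other causes. GC content bias may contribute, because the shared difference fell with GC content (Spearman rho -0.456, across genes), and a separate culture or day for replicate 3, which the labels do not give, was not tested.

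Other splits of the libraries are too few for a share under 0.05, since 3 against 3 libraries make 10 splits and swaps within 3 pairs make 4. Without the block the real split called 0 genes and the highest other split 0, so 10 of 10 splits gave as many. In the paired fit the real split called 406 genes and the highest other split 0, so 1 of 4 gave as many. For gene lists without the block, the real split put 14 past the threshold and the highest other split 14, so 2 of 10 gave as many. That other split set control 1, JOA 1 and JOA 2 against control 2, control 3 and JOA 3, which keeps both libraries numbered 1 together and both numbered 3 together. The other splits without the block put from 6 to 14 lists past the threshold. With the replicate block 17 lists passed in the real grouping, and 6, 10 and 8 passed in the swaps within pairs. Many lists thus passed at the preset correlation under any grouping. The other splits and swaps mix the groups unevenly, so they still hold part of any difference between the groups.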
